A study of Mus musculus with 7 samples.

How the data were processed

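RNA of pancreatic islets from mice aged 7 days was measured by sequencing of ribosome-depleted total RNA in 7 libraries, 3 from Nrf2lox/lox mice (control) and 4 from mice lacking Nrf2 in β-cells (βNrf2KO). Per the labels' protocols each library was made from a pool of RNA of 5 animals, although the sample titles number them as single mice. The p-values therefore measure the spread between pools, not between animals. Control pools carry the numbers 1, 2 and 4 and βNrf2KO pools the numbers 1, 2, 3 and 4.

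The deposited values are raw counts per gene. Per the submitters' processing notes, the authors used bcl2fastq 2.20, Trimmomatic 0.36, STAR 2.5.2b and featureCounts of Subread 1.5.2. The strand setting, the rule for reads with several matches and the annotation release were not given in the sources used here. The notes name a newer genome build, but the exon coordinates in the files are those of GRCm38. Of 49056 gene IDs shared with GENCODE M21, 44858 (91.4%) had the same start and end, so coordinates are given in GRCm38 as the files print them. Each file holds 49316 entries, of which 49315 are mouse genes and 1 is a Cre recombinase sequence. The Cre entry was left out of library sizes and tests, and a combined count table that holds the same columns was not used here. Symbols were taken from the reference table of gene names, which matched 48970 IDs and left 345 unmatched, and 132 symbols were shared by more than 1 ID.

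Total counts per pool ran from 18187382 to 25373105. A count of 0 allows up to 3 counts, which was 0.118 to 0.139 CPM in the control pools. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules. The common biological coefficient of variation was 0.280.

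Genes were tested with edgeR 4.0.16 (R 4.3.3 and the data.table package, version 1.17.8), using TMM normalization, filterByExpr by group, the robust quasi-likelihood fit and its two-sided test with Benjamini-Hochberg adjustment over 19893 tested genes. The threshold was an adjusted p of 0.05. Log2 fold changes are βNrf2KO minus control, and errors beside them are standard errors (SE) of that fit over 3 control and 4 βNrf2KO pools. Values given with the block carry the SE of the block fit described below. Errors beside group means are standard deviations (SD). Single measures were compared by an exact two-sided permutation test over the 35 splits of the 7 pools into 3 and 4, doubling the smaller tail. An exact test in this design cannot go below p = 0.0571.

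A total of 35 gene lists, the tests and most alternatives were fixed before the data were examined. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, which compares a list with all other tested genes, with Benjamini-Hochberg adjustment over the 35 lists. Beside it stood camera with the correlation estimated per list and fry, which asks whether the genes of a list move on balance in 1 direction. Members past the threshold were counted over all tested genes and adjusted over the list alone.

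The genes named were chosen by rule. Nfe2l2, Keap1, Ins1, Ins2, Gcg, Sst and Ppy were always named. With fewer than 5 genes past the threshold in a direction, the rule named the 5 with the smallest unadjusted p in that direction, among genes with a mean log2 CPM of at least 1, groups that did not overlap and a symbol that is not a predicted-gene name. Up to 4 members with the smallest p were named per list, or with the highest mean log2 CPM for lists of cell types. Genes called by an alternative only, and Nqo1 and Prph, fall outside the rule and were chosen after their values were seen.

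The pool numbers were checked on the data, since the labels do not say what they stand for. After removal of each group's mean, pools with the same number correlated across genes at r = 0.376 (number 1), 0.229 (number 2) and 0.323 (number 4). Pools with different numbers ranged from -0.353 to 0.241. Each of the 6 pools with a partner correlated best with its own number, although genes are not independent replicates. This is limited evidence, since control pool 4 and βNrf2KO pool 3 (r = 0.241) correlated more than the pools of number 2. The numbers were therefore treated as possible pairs only, and a fit with the pool number as a block was an alternative. Pool 3 has no control partner, so the group difference in the block fit rests on pairs 1, 2 and 4.

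Alternatives for the gene tests were RLE and upper-quartile normalization, library sizes without the 20 highest genes, no filter, a filter of at least 1 CPM in at least 3 pools, DESeq2 1.42.0, limma-voom with quality weights, the pool number as a block, the mean of the acinar list as a covariate, 1 surrogate variable (sva 3.50.0), leaving out each pool, and a threshold of 0.1. Gene lists were also tested with RLE normalization, the 1 CPM filter, the block, the acinar covariate and without each pool. Xist as a covariate, and the block combined with an estimated correlation or with fry, were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).

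The gene test was tested on simulated data of 19893 genes with the same group sizes, in 5 runs with 200 changed genes each. Genes were drawn independently, without differences that many genes of a pool share, and changes were placed in genes with a mean above 1 CPM. It recovered 35.2% of 2-fold and 88.2% of 4-fold changes and made 52 false calls over the 5 runs, and 3 calls over 5 runs without any change. With genes simulated as independent of each other, a list of 40 genes shifted by 0.5 on the log2 scale was called (adjusted p = 2.99e-22) and 0 of 34 unshifted lists were called by camera at the preset correlation.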

Results

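Gene expression was measured in islets of 7-day-old mice in 3 control pools and 4 βNrf2KO pools, each made from RNA of 5 animals. Control pools 1, 2 and 4 held 21603654, 24271929 and 25373105 counts, and βNrf2KO pools 1, 2, 3 and 4 held 18187382, 19158804, 19452226 and 20847474. Every control pool was deeper than every βNrf2KO pool, with a ratio of the βNrf2KO to the control mean of 0.818 (exact permutation p = 0.0571, the smallest this design allows). Between 25979 and 29149 genes had at least 1 count in a pool. The Cre recombinase sequence, the enzyme that removes loxP-flanked DNA, had 24, 23, 46 and 73 counts in βNrf2KO pools 1, 2, 3 and 4 and 0 counts in each of the 3 control pools. This was 2.10 ± 1.07 CPM (SD, n = 4), at least 16.5-fold higher than the mean limit that 0 counts allow per control library (exact permutation p = 0.0571).

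The series asks how Nrf2, a transcription factor of the response to oxidative stress, stimulates β-cell proliferation in neonatal islets. Nfe2l2, the gene of Nrf2 (ENSMUSG00000015839, chromosome 2, 75675513 to 75704641, minus strand, GRCm38), was read at 6.43, 5.44 and 5.60 log2 CPM in control pools 1, 2 and 4. It was read at 6.07, 5.86, 6.08 and 5.88 log2 CPM in βNrf2KO pools 1, 2, 3 and 4. The group means were 5.82 ± 0.53 (SD, n = 3) and 5.97 ± 0.12 (SD, n = 4), which overlapped (exact permutation p = 0.629). Its log2 fold change was 0.08 ± 0.23 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.911). The sign turned without control pool 2 or control pool 4, over a range of -0.10 to 0.45 when each pool was left out. Counts per gene include exons outside a deletion and cells other than β-cells, so they do not check the deletion itself. Keap1, whose protein holds Nrf2 in the cytoplasm for degradation, differed by 0.16 ± 0.20 (adjusted p = 0.788 by the same edgeR test), over a range of -0.02 to 0.28 with the sign turned without control pool 2.

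No gene passed the threshold in the comparison of βNrf2KO with control islets. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 19893 genes passed and the smallest adjusted p was 0.571. At unadjusted p under 0.05 there were 1683 genes, 642 higher and 1041 lower in βNrf2KO, where chance alone gives 995. That number was 2415 with the pool number as a block, 1198 higher and 1217 lower, so the excess of lower genes was absent there, and 571 with 1 surrogate variable, 164 higher and 407 lower. DESeq2 called 2 genes, Hmcn2 and Stum, both lower, and limma-voom called 0. With the pool number as a block edgeR called 14 genes, 1 higher and 13 lower. Without control pool 4 it called 1 gene, Hmcn2 (log2 fold change -2.90, adjusted p = 0.0346). The number at unadjusted p under 0.05 was 2893 without control pool 1, 475 without control pool 2, 3446 without control pool 4, 783 without βNrf2KO pool 3 and 820 without βNrf2KO pool 4.

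The genes with the smallest p among those whose pools did not overlap between groups are named here, and none passed the threshold (edgeR quasi-likelihood test, each adjusted p = 0.571). Hmcn2, which encodes the extracellular matrix protein hemicentin 2, differed by -2.48 ± 0.45 on the log2 scale. Its adjusted p was 0.000751 by DESeq2 and 0.0482 with the block. Stum, a homologue of a fly mechanotransduction gene, differed by -1.18 ± 0.23, with an adjusted p of 0.0451 by DESeq2. Myh11, the heavy chain of smooth muscle myosin, differed by -1.20 ± 0.28, and by -1.07 ± 0.17 with the block (adjusted p = 0.0482). Kif26b, a kinesin-like gene of developing mesenchyme, differed by -0.97 ± 0.21 and Scarna2, a small Cajal body RNA, by -0.89 ± 0.20. Among the genes with higher values, Lrrc15, a membrane protein of matrix-producing fibroblasts, differed by 1.77 ± 0.42. Ero1l, the oxidase that renews disulfide bonds in the endoplasmic reticulum, differed by 1.33 ± 0.32. Bnip3, a mitophagy receptor induced by low oxygen, differed by 1.00 ± 0.24, the secreted phosphoprotein Spp1 by 0.95 ± 0.23 and Erg28, a scaffold of sterol synthesis, by 0.77 ± 0.19.

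**Figure D1:**
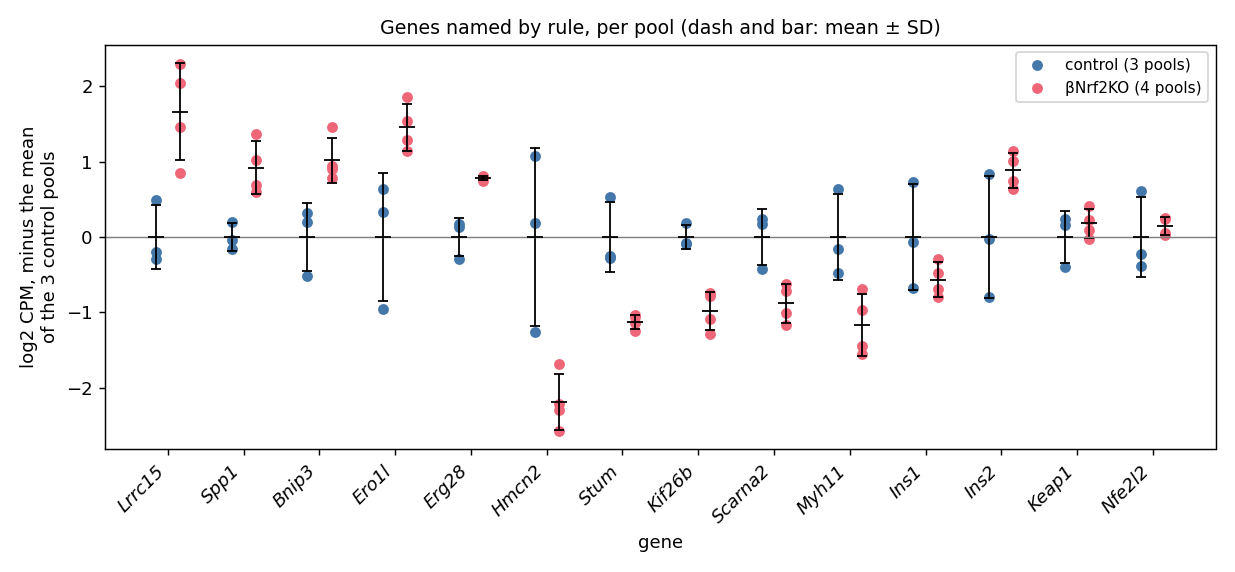
Expression of the genes named by rule in each of the 3 control and 4 βNrf2KO pools, as log2 CPM minus the mean of the control pools (points: pools, dash and bar: mean ± SD). The pools of both groups do not overlap for Lrrc15, Spp1, Bnip3, Ero1l, Erg28, Hmcn2, Stum, Kif26b, Scarna2 and Myh11, and they overlap for Nfe2l2.

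The other genes called with the block were chosen after their values were seen. Arhgap36, a gene expressed in endocrine tissue, was the only gene called higher (1.18 ± 0.18 with the block, adjusted p = 0.0482 by edgeR, against 1.28 ± 0.33 without it). Stmn2, a neuronal microtubule regulator, was called lower (-1.38 ± 0.19 with the block, adjusted p = 0.0469), as was the predicted gene Gm21269 (-2.14 ± 0.33, adjusted p = 0.0482). The remaining calls were in the mitochondrial genome. These were the mRNAs mt-Nd3 (-1.68 ± 0.21, adjusted p = 0.0244), mt-Atp8 (-1.72 ± 0.24, adjusted p = 0.0469) and mt-Atp6 (-1.51 ± 0.23, adjusted p = 0.0482). The others were the transfer RNAs mt-Tp (-1.87 ± 0.20, adjusted p = 0.0160), mt-Ta (-1.97 ± 0.25, adjusted p = 0.0244), mt-Tl1 (-1.46 ± 0.22), mt-Tm (-1.69 ± 0.26), mt-Tw (-2.17 ± 0.34) and mt-Tq (-1.77 ± 0.28), the last 4 with adjusted p = 0.0482. Counts per pool were low for mt-Tm (38 to 206), mt-Tw (11 to 190) and mt-Tq (21 to 141). The mRNAs mt-Atp8, mt-Atp6 and mt-Nd3 lie in a stretch with a nuclear copy on chromosome 1 (24611535 to 24616197, GRCm38). These mRNAs held 43 to 1339 counts per pool, against 160690 to 982510 for mt-Nd2 outside that stretch. Most of their reads were therefore probably not counted, and the calls rest on the remainder.

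Of the 35 gene lists, camera at the preset correlation called 15, 6 higher and 9 lower in βNrf2KO. With an estimated correlation none of these calls held, with a smallest adjusted p of 0.752. The adjustment gave all 15 called lists this same value, so the 0.752 beside a list is shared. The test fry called 0 lists, with a smallest adjusted p of 0.730. With the block camera called 14 lists, 13 of them also called without it, and without βNrf2KO pool 1 it called 9. Over all tested genes 0 list members passed the threshold, and adjusted over the list alone 5 lists had a member that passed and 30 had none. These counts cover only genes found in the files under the symbol listed.

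Targets of Nrf2 were asked about first, since the labels describe a deletion of their activator in β-cells, which the counts do not check. Epha2, a receptor tyrosine kinase, differed by -0.88 ± 0.27 and Txn1, the cytosolic thioredoxin, by -0.55 ± 0.20. Gclm, a subunit of the enzyme that begins glutathione synthesis, differed by 0.54 ± 0.20 (edgeR, adjusted p = 0.571 for each of these). Nqo1, a quinone reductase often read as a measure of Nrf2 activity, differed by -0.05 ± 0.36 (adjusted p = 0.969) and was chosen after its values were seen. It was 0.02 with the block, and its sign also turned without control pool 4 (0.47) or βNrf2KO pool 2 (0.01). Of 47 targets tested, 24 were higher and 23 lower, with a median log2 fold change of 0.01 (camera, adjusted p = 0.642). The direction of this list turned without control pool 2 (adjusted p = 0.948). No target passed over all genes and 0 adjusted over the list alone, and 1 higher and 2 lower had unadjusted p under 0.05. Of 37 genes of glutathione and thioredoxin redox, 19 were higher and 18 lower (median 0.01, camera adjusted p = 0.356, 0 members adjusted over the list alone). They included the peroxidases Prdx6 (0.46 ± 0.19) and Gpx2 (0.88 ± 0.40), both with adjusted p = 0.571 by edgeR. Without control pool 4 these were 0.71 and 1.59, and the lowest values were 0.34 for Prdx6 without control pool 2 and 0.60 for Gpx2 without control pool 1.

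Proliferation, the process named in the series design, was read from lists of cell cycle genes. The counts come from whole islets, so they do not tell β-cells from other dividing cells. Tk1, a thymidine kinase of S phase, differed by -0.72 ± 0.23 and Rfc5, a loader of the replication clamp, by -0.50 ± 0.19. Foxm1, a transcription factor that drives mitotic genes, differed by -0.47 ± 0.19, the phosphatase Cdc25b by -0.44 ± 0.20 and the proliferation antigen Mki67 by -0.35 ± 0.17. None of these passed the threshold (edgeR, adjusted p = 0.571 each), nor did the mitotic kinase Cdk1 (-0.41 ± 0.23, adjusted p = 0.584). The G2 and M phase list was called lower, with 40 of 55 genes lower and a median of -0.18 (camera, adjusted p = 0.00484), and adjusted p = 0.752 with an estimated correlation. The call ended without βNrf2KO pool 1 (adjusted p = 0.0771) or βNrf2KO pool 2 (0.0657), and the direction turned without control pool 4 (0.640). Replication-dependent histones, made in S phase, were called lower, with 38 of 43 genes lower and a median of -0.29 (adjusted p = 2.45e-05), and adjusted p = 0.752 with an estimated correlation. That call ended without control pool 4 (adjusted p = 0.402). Among the histone genes Hist1h1e differed by -0.70 ± 0.25, Hist1h2bb by -0.68 ± 0.29 and Hist1h3c by -0.47 ± 0.21. The means of both lists were lower in pairs 2 and 4, and the difference in pair 1 was 0.00 for G2 and M phase and -0.05 for the histones.

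The S phase list was not called (29 of 48 genes lower, median -0.08, camera adjusted p = 0.168). It was called lower with the block (adjusted p = 0.0220, against adjusted p = 0.857 with the block and an estimated correlation). Its list mean was lower in pairs 1 and 4 (-0.20 and -0.45 log2 CPM) and higher in pair 2 (0.25). The list was also called lower without control pool 1 (0.0203), control pool 2 (0.00516), βNrf2KO pool 2 (0.0303) or βNrf2KO pool 3 (0.0157), and turned without control pool 4 (0.346). G1 cyclins and cell cycle inhibitors had a median of -0.00 and a mean of -0.04 while the test pointed higher (23 genes, camera adjusted p = 0.957). The test of this list turned with the block (adjusted p = 0.571) and without control pools 1 or 2 or βNrf2KO pools 2, 3 or 4 (adjusted p = 0.916, 0.943, 0.970, 0.617 and 0.893). In it, the inhibitor Cdkn1b differed by 0.42 ± 0.17 and Cdkn1c by -0.58 ± 0.30 (edgeR adjusted p = 0.571 and 0.572). Growth factor signalling of neonatal β-cells was not called (22 of 36 genes lower, median -0.12, camera adjusted p = 0.883). Its members with the smallest p included Nfatc4 (-0.83 ± 0.30) and Nfatc1 (-0.51 ± 0.21), calcineurin-dependent transcription factors, and Egfr (0.68 ± 0.27) and Ctnnb1 (0.64 ± 0.25), the receptor of epidermal growth factor and β-catenin. The direction of this list turned without control pool 1 (0.405), control pool 2 (0.943) or βNrf2KO pool 4 (0.822), and with the block 3 members passed adjusted over the list alone, against 0 without it. The prolactin and growth hormone STAT5 response was not called (17 genes, median 0.11, camera adjusted p = 0.714) and turned without control pool 2 (0.900). Its feedback inhibitors Cish and Socs2 differed by -0.51 ± 0.17 and -0.42 ± 0.17 (edgeR adjusted p = 0.571 each). Of the 6 lists of the cell cycle and its signals, 0 members passed adjusted over the list alone.

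Mitochondria were examined next, since the series title speaks of their biogenesis and function. All 13 mRNAs of the mitochondrial genome were lower in βNrf2KO, with a median log2 fold change of -1.49, and the list was called lower (camera, adjusted p = 5.11e-08), with adjusted p = 0.752 with an estimated correlation. Of these, mt-Nd2 differed by -1.47 ± 0.55, mt-Cytb by -1.49 ± 0.56, mt-Nd1 by -1.45 ± 0.56 and mt-Nd3 by -1.81 ± 0.58, subunits of respiratory complexes I and III (edgeR adjusted p = 0.571 each). Over all genes 0 of the 13 passed, and adjusted over the list alone 9 passed, all lower. With the block 3 passed over all genes and 13 adjusted over the list alone. The call stayed without any 1 of the 7 pools (largest adjusted p = 0.000378), but the median was -0.90 without control pool 2. The mitochondrial genome took 43.0%, 51.8% and 14.6% of counts in control pools 1, 2 and 4, and 27.7%, 22.4%, 20.7% and 10.02% in βNrf2KO pools 1, 2, 3 and 4. The means were 36.5% ± 19.4 (SD, n = 3) and 20.2% ± 7.43 (SD, n = 4), which overlapped (exact permutation p = 0.229). The share was lower in βNrf2KO in each pair of pools, by -15.3, -29.4 and -4.60 percentage points for numbers 1, 2 and 4.

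Lists of nuclear genes of the mitochondrion had medians between -0.01 and 0.15. Atp5j2, a subunit of ATP synthase, differed by -0.56 ± 0.19 and Ndufc2 of complex I by 0.49 ± 0.23 (edgeR adjusted p = 0.571 each). The list of nuclear-encoded OXPHOS subunits was not called (51 of 76 genes higher, median 0.07, camera adjusted p = 0.335). It was called higher without control pool 4 (adjusted p = 0.000135) and turned without control pool 2 (0.0947). Mitochondrial biogenesis and mtDNA maintenance was not called (22 of 35 genes higher, median 0.08, adjusted p = 0.186). Its regulators of mitochondrial transcription Mterf1a and Mterf3 differed by 1.25 ± 0.41 and 0.35 ± 0.18. The mitochondrial ribosome was not called (45 of 77 genes higher, median 0.05, adjusted p = 0.134), and was called higher without control pool 4 (0.0112) or βNrf2KO pool 4 (0.0395). In it Mrpl50 differed by 0.64 ± 0.27 and Mrps30 by 0.56 ± 0.24. Mitochondrial dynamics and mitophagy was not called (18 of 28 genes higher, median 0.08, adjusted p = 0.155) and was called higher without control pool 4 (0.0447). The 1 member that passed adjusted over the list alone was Bnip3 (adjusted p = 0.0443), while the inner membrane proteases Yme1l1 and Afg3l2 differed by 0.48 ± 0.18 and -0.43 ± 0.18. TCA cycle and pyruvate metabolism was called higher (29 of 37 genes higher, median 0.15, camera adjusted p = 0.00501), with adjusted p = 0.752 with an estimated correlation. This call ended with the acinar covariate (0.198) and without control pool 1 (0.290) or control pool 2 (0.0851), and the list mean was lower in pair 4 (-0.05). It included Pdk1, which restrains pyruvate entry (0.61 ± 0.22), and the dehydrogenase Mdh1 and fumarase Fh1 (0.47 ± 0.18 and 0.45 ± 0.19). Fatty acid oxidation and ketogenesis had a median of -0.01 and a mean of -0.02 while the test pointed higher (29 genes, adjusted p = 0.645), and it turned without control pool 2 (0.883). Bnip3 apart, 0 members of these lists of nuclear genes passed when adjusted over the list alone.

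**Figure D2:**
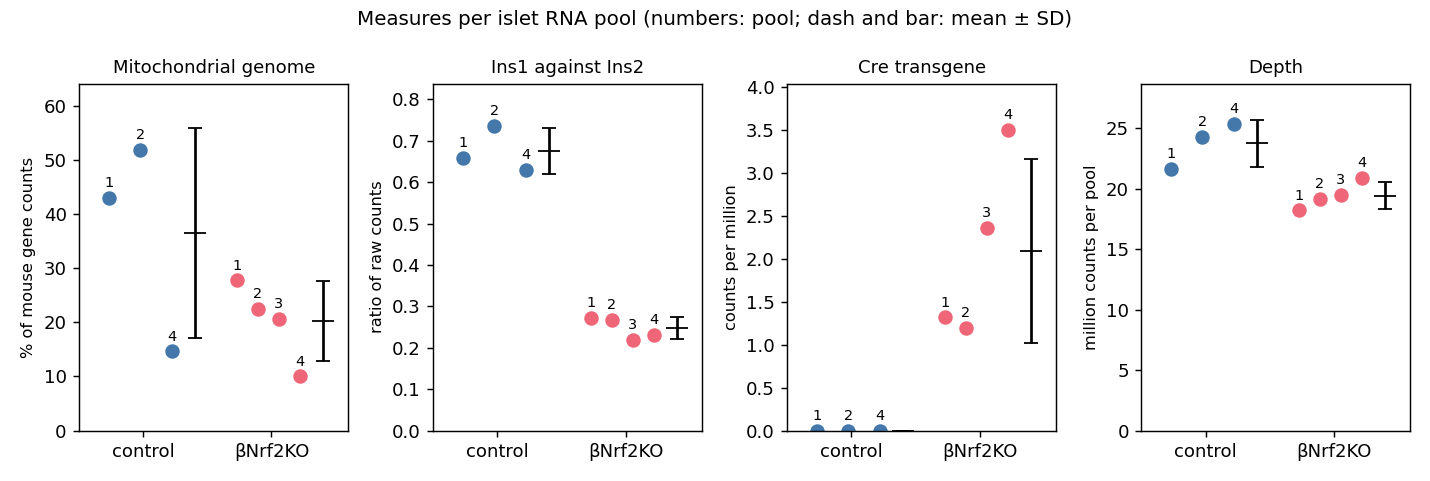
Share of counts from the mitochondrial genome (%), ratio of Ins1 to Ins2 counts, Cre expression (CPM) and depth (counts, in units of 1e6) in the 3 control and 4 βNrf2KO pools (points: pools with their numbers, dash and bar: mean ± SD). The ratio of Ins1 to Ins2 lies between 0.629 and 0.736 in control pools and between 0.219 and 0.273 in βNrf2KO pools, while the mitochondrial shares of the groups overlap.

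Islet hormones and β-cell genes were compared to ask whether β-cell identity differed. Ins1 (ENSMUSG00000035804, chromosome 19, 52264323 to 52265456) differed by -0.66 ± 0.31 and Ins2 by 0.75 ± 0.36, the insulin genes of the mouse, and neither passed (edgeR adjusted p = 0.571 each). When each pool was left out Ins1 ranged from -0.94 (without control pool 2) to -0.22 (without control pool 4), and Ins2 from 0.43 to 1.26 without the same pools. The ratio of Ins1 to Ins2 counts was 0.674 ± 0.0553 (SD, n = 3) in control and 0.248 ± 0.0268 (SD, n = 4) in βNrf2KO pools, with no overlap (exact permutation p = 0.0571, the smallest this design allows). Glucagon (Gcg) differed by 0.64 ± 0.54 (adjusted p = 0.685), between 0.31 without βNrf2KO pool 3 and 1.45 without control pool 4. Somatostatin (Sst) differed by -0.34 ± 0.22 (adjusted p = 0.625) and pancreatic polypeptide (Ppy) by 0.05 ± 0.37 (adjusted p = 0.965 by edgeR). The sign of Ppy turned with the block (-0.22) and without control pool 1, βNrf2KO pool 2 or βNrf2KO pool 3, over a range of -0.20 to 0.31. The list of β-cell identity and function was called higher, with 27 of 39 genes higher and a median of 0.25 (camera, adjusted p = 0.000808), and adjusted p = 0.752 with an estimated correlation. The call ended without control pool 1 (adjusted p = 0.0745). Its mean was higher in each of the 3 pairs. Among its members the ion channel Trpm5 differed by 0.71 ± 0.18, the granule protein Sytl4 by 0.81 ± 0.27, the gap junction gene Gjd2 by 0.74 ± 0.30 and Mafa, a transcription factor of mature β-cells, by -0.78 ± 0.22 (edgeR adjusted p = 0.571 each). Adjusted over the list alone 0 of its members passed, and with the block 4 higher and 1 lower passed on that adjustment.

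Immature β-cell and disallowed genes were not called (16 of 26 lower, median -0.14, camera adjusted p = 0.356), with the growth factor Igf2 at -0.63 ± 0.27. Alpha-cell markers were not called (12 of 17 higher, median 0.07, adjusted p = 0.459). They were called higher without control pool 4 (0.00246), and turned with the block (adjusted p = 0.571) and without control pool 1 (0.290) or βNrf2KO pool 3 (0.771). Delta, PP and epsilon markers had a median of 0.05 and a mean of 0.01 while the test pointed lower (12 genes, adjusted p = 0.930), and turned without control pool 4 (0.167) or βNrf2KO pool 1 (0.316). In these 3 lists 0 members passed adjusted over the list alone.

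Other cell types of the islet preparation were read from marker lists to ask whether cell composition differed between pools. Acinar markers were lower for all 27 genes, with a median of -0.88, and were called lower (camera, adjusted p = 0.00215), with adjusted p = 0.752 with an estimated correlation. That call ended without control pool 1 (adjusted p = 0.915) or βNrf2KO pool 4 (0.0712). Clps, a cofactor of pancreatic lipase, differed by -1.19 ± 0.49 and the protease Ctrb1 by -0.78 ± 0.70 (edgeR adjusted p = 0.571 and 0.707), and Ctrb1 turned to 0.10 without control pool 1. Acinar markers took 0.0544%, 0.0170% and 0.0144% of counts in control pools 1, 2 and 4, and between 0.0130% and 0.0398% in βNrf2KO pools. The mean of the acinar list differed by -1.76, 0.42 and -0.24 log2 CPM in pairs 1, 2 and 4. Mesenchymal and stellate markers were called lower, with 27 of 28 genes lower and a median of -0.57 (camera, adjusted p = 5.51e-07), and adjusted p = 0.752 with an estimated correlation. At the preset correlation of 0.01 the list stayed called lower without any 1 of the 7 pools (camera, largest adjusted p = 0.0359). Its estimated correlation was 0.744. Its mean was lower in pairs 1 and 2 and higher by 0.10 in pair 4. In it the pericyte gene Rgs5 differed by -0.80 ± 0.30, the collagen Col1a1 by -0.69 ± 0.41 (adjusted p = 0.601) and the filament gene Vim by -0.32 ± 0.23 (adjusted p = 0.642). These sizes hung on single pools, with Rgs5 at -0.33 without control pool 2 and -1.11 without control pool 4, Col1a1 at -0.33 without control pool 1 and -1.07 without βNrf2KO pool 2, and Vim at -0.09 without control pool 1 and -0.56 without control pool 4. The matrix gene Sparc differed by -0.02 ± 0.19 (adjusted p = 0.970), with a sign that turned with the block (0.01) and without control pool 1, control pool 2 or βNrf2KO pool 1, up to 0.10.

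Macrophage and leukocyte markers were called lower (22 of 25 genes, median -0.23, camera adjusted p = 0.0192), with adjusted p = 0.752 with an estimated correlation. The call ended with the block (adjusted p = 0.333), the acinar covariate (0.447) or the Xist covariate (0.361). It also ended without control pool 1 (0.853), βNrf2KO pool 1 (0.0970) or βNrf2KO pool 3 (0.306). The list mean was lower in pair 1 (-0.93 log2 CPM) and higher in pairs 2 and 4 (0.26 and 0.17). Csf1r, the receptor that sustains macrophages, differed by -0.46 ± 0.21 (edgeR adjusted p = 0.571). Neural and Schwann markers were called lower (13 of 17 genes, median -0.38, camera adjusted p = 0.00805), with adjusted p = 0.752 with an estimated correlation. That call ended without control pool 2 (0.0851), control pool 4 (0.113) or βNrf2KO pool 1 (0.101). Their most abundant genes Ret and Mbp differed by 0.27 ± 0.26 and 0.11 ± 0.16 (edgeR adjusted p = 0.724 and 0.812). The 1 neural gene that passed adjusted over the list alone was the peripheral neuron filament Prph (-1.09 ± 0.28), chosen after its values were seen, and with the block 3 passed. Ductal markers were not called (9 of 18 higher, median 0.16, camera adjusted p = 0.175), with Cldn4 at 0.61 ± 0.26 and Krt7 at 0.40 ± 0.21. Spp1 was the 1 ductal gene past the threshold adjusted over the list alone, and with the block 2 passed. Endothelial markers were not called (14 of 22 higher, median 0.07, adjusted p = 0.217), with the adhesion gene Pecam1 at 0.30 ± 0.16 (edgeR adjusted p = 0.585). Erythroid markers were not called (6 of 10 lower, median -0.24, adjusted p = 0.227). They were called lower without control pool 4 (0.0198) or βNrf2KO pool 2 (0.000365) and turned without control pool 2 (0.943). In the other cell type lists 0 members passed adjusted over the list alone, while with the block 6 mesenchymal and 2 acinar genes passed, all lower.

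Stress, metabolism and protein synthesis were read from the remaining lists. Hypoxia and glycolysis genes were called higher, with 28 of 33 genes higher and a median of 0.39 (camera, adjusted p = 1.42e-10), and adjusted p = 0.752 with an estimated correlation. The call stayed without any 1 of the 7 pools (largest adjusted p = 3.72e-05), and the list mean was higher in each of the 3 pairs. The list means of the groups overlapped, at 4.56 ± 0.44 (SD, n = 3) and 5.06 ± 0.19 (SD, n = 4) log2 CPM (exact permutation p = 0.171). In this list 3 genes passed adjusted over the list alone, the glycolytic enzymes Eno1 (0.87 ± 0.22) and Tpi1 (0.67 ± 0.18) and Bnip3, each with adjusted p = 0.0295, and with the block 9 passed. Aldoa, another glycolytic enzyme, differed by 0.63 ± 0.20. Cytosolic ribosomal proteins were called lower, with 73 of 79 genes lower and a median of -0.23 (camera, adjusted p = 4.23e-11), and adjusted p = 0.752 with an estimated correlation. The call stayed without any 1 of the 7 pools (largest adjusted p = 9.45e-06). Their list mean was 5.54 ± 0.09 (SD, n = 3) in control and 5.30 ± 0.10 (SD, n = 4) in βNrf2KO pools, without overlap (exact permutation p = 0.0571). In this list Rpl36 differed by -0.63 ± 0.23, Rpl37a by -0.54 ± 0.18 and Rps12 by -0.43 ± 0.16 (edgeR adjusted p = 0.571 each). Adjusted over the list alone 0 ribosomal proteins passed, and 14 had unadjusted p under 0.05, all lower.

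**Figure D3:**
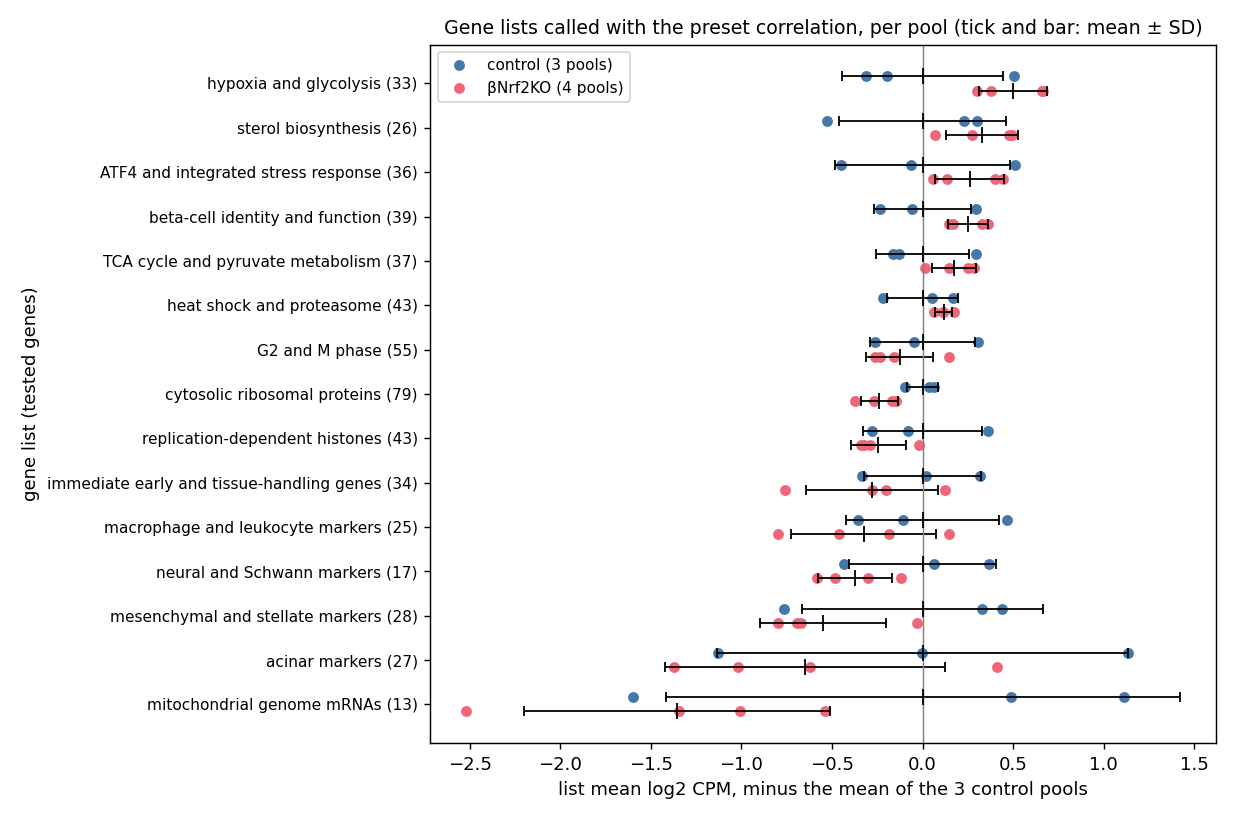
Mean log2 CPM of each gene list called by camera at the preset correlation, minus the mean of the 3 control pools, in each of 3 control and 4 βNrf2KO pools (points: pools, tick and bar: mean ± SD, in brackets: genes tested). The pools of both groups are apart for cytosolic ribosomal proteins and overlap for the other 14 lists.

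ATF4 and the integrated stress response was called higher (28 of 36 genes higher, median 0.23, camera adjusted p = 0.00454), with adjusted p = 0.752 with an estimated correlation. The call ended without control pool 2 (0.309), control pool 4 (0.0735) or βNrf2KO pool 1 (0.0967), and the list mean was lower in pair 1 (-0.07). Its members moved both ways: Asns, which makes asparagine, differed by 0.67 ± 0.29, while the transcription factors Ddit3 and Atf3 differed by -0.60 ± 0.22 and -0.66 ± 0.29 (edgeR adjusted p = 0.571 each). Adjusted over the list alone 0 passed, and with the block 3 higher and 3 lower passed. The unfolded protein response was not called (19 of 28 genes higher, median 0.11, adjusted p = 0.183), and was called higher without control pool 4 (0.00544) or βNrf2KO pool 4 (0.0226). The chaperone cofactor Dnajb9 differed by 0.99 ± 0.27 and Herpud1, a gene of protein degradation, by -0.67 ± 0.24, with 0 members adjusted over the list alone and 1 with the block. Ero1l (1.33 ± 0.32) was listed under another symbol, Ero1a, which the files do not hold. It was therefore not among the 28 genes tested, and the values of this list leave it out. Heat shock and proteasome genes were called higher (33 of 43, median 0.14, camera adjusted p = 0.0319), with adjusted p = 0.752 with an estimated correlation. That call ended with the block (0.107) or the acinar covariate (0.0979). It also ended without control pool 1 (0.0774), control pool 2 (0.694), βNrf2KO pool 1 (0.101), βNrf2KO pool 2 (0.0657) or βNrf2KO pool 3 (0.114). The list mean was lower in pair 4 (-0.10). The proteasome subunit Psmd12 differed by 0.48 ± 0.19 and the small heat shock gene Cryab by -0.82 ± 0.33. The p53 response and apoptosis was not called (19 of 33 genes higher, median 0.03, adjusted p = 0.426), with the p53 target Ccng1 at 0.71 ± 0.21. In these last 2 lists 0 members passed adjusted over the list alone.

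Immediate early and tissue-handling genes, which respond within minutes to cell isolation, were called lower (28 of 34 genes, median -0.28, camera adjusted p = 0.000603), with adjusted p = 0.752 with an estimated correlation. The call ended with the Xist covariate (0.0527) and without control pool 4 (0.241) or βNrf2KO pool 1 (0.117), and the list mean was higher in pair 2 (0.10). The transcription factors Maff (-0.70 ± 0.20), Klf6 (-0.56 ± 0.21), Junb (-0.58 ± 0.24) and Fosb (-0.94 ± 0.39) were among its members (edgeR adjusted p = 0.571 each). Junb ranged from -0.81 without control pool 1 to -0.37 without control pool 4, and Fosb from -1.31 without control pool 1 to -0.40 without control pool 2. Adjusted over the list alone 0 passed, and with the block 5 passed. Sterol biosynthesis was called higher (21 of 26 genes, median 0.31, camera adjusted p = 0.00215), with adjusted p = 0.752 with an estimated correlation, and that call ended without control pool 2 (0.382). The sterol list mean was lower in pair 4 (-0.23). Its enzymes Sc5d and Fdft1 differed by 0.69 ± 0.30 and 0.48 ± 0.23, with 0 members adjusted over the list alone. The interferon and NF-kB response was not called (21 of 40 genes higher, median 0.09, adjusted p = 0.410) and its direction turned with the block (0.744) and without control pool 4 (0.628). Its members went both ways: the interferon-induced genes Isg15, Ifit1 and Oasl2 differed by 1.75 ± 0.47, 1.75 ± 0.50 and 1.16 ± 0.36, and the chemokine Cxcl2 by -1.48 ± 0.38 (edgeR adjusted p = 0.571 each). In that list 0 members passed adjusted over the list alone, and 1 passed with the block.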

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

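No explanation was tested for the values in this part, and Stmn2 and mt-Tp were chosen after their values were seen. In each group of 4 βNrf2KO pools, the distance of the highest or lowest pool to its nearest neighbour was set against the range of the group. Of 154 such groups 5 had a pool far from the others, and chance flags about 1 in 20. Foxm1 stood at 4.92 log2 CPM in βNrf2KO pool 3, where the other 3 pools lay between 4.54 and 4.57. Stmn2 stood at 4.38 in the same pool, against 3.14 to 3.34 in the others. The mean of the replication-dependent histones was also high in βNrf2KO pool 3, at 2.80 log2 CPM against 2.48 to 2.53. For the mesenchymal and stellate list the mean was 5.77 log2 CPM in βNrf2KO pool 2, against 5.01 to 5.14. The transfer RNA mt-Tp stood at 6.12 log2 CPM in βNrf2KO pool 4, against 7.79 to 8.09 in the others.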

How the results depend on the processing

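The Xist covariate and the block combined with an estimated correlation or fry were chosen only after seeing the data. The count of genes past the threshold, 0 by edgeR (1683 at unadjusted p under 0.05), was also 0 with RLE, upper-quartile factors, library sizes without the 20 highest genes, no filter, the 1 CPM filter, limma-voom, the acinar and Xist covariates, 1 surrogate variable and a threshold of 0.1. It was 2 with DESeq2, 14 with the block and 0 to 1 when each pool was left out. Of the comparisons of named genes with their alternatives, 1897 kept direction and side of the threshold, 17 gained a call and 23 turned. Of those of lists 415 kept both, 15 gained a call, 92 lost it and 38 turned. Only the mitochondrial mRNA, mesenchymal, hypoxia and ribosomal protein lists kept their call in all 12 alternatives at the preset correlation. The number of called lists was 0 with an estimated correlation or fry, with or without the block, 14 with the block, and 9 to 16 when each pool was left out. Each of the 15 called lists had adjusted p = 0.752 with an estimated correlation, 0.730 with fry and 0.857 with the block and an estimated correlation. The adjustment makes these values shared, and the unadjusted p of the 15 lists differed. By fry they ran from 0.0231 (ribosomal proteins) and 0.0479 (hypoxia) to 0.468 (acinar). By camera with an estimated correlation they ran from 0.0701 (hypoxia) to 0.471 (heat shock). With the block and fry it was 0.758 for the mitochondrial mRNA, neural, hypoxia and ribosomal protein lists, 0.789 for β-cell identity and 0.815 for the others. The block also gave adjusted p = 0.0220 for S phase (a call), 0.333 for macrophages and 0.107 for heat shock (calls lost), and it changed the call of no other list. It turned G1 and alpha-cell markers (0.571 each) and interferon (0.744), also with an estimated correlation (0.857 for G1 and alpha, 0.902 for interferon) and with fry (0.815 for these 3 and 0.9995 for OXPHOS). The acinar covariate gave 0.0266 for S phase, and ended the calls of TCA (0.198), macrophages (0.447) and heat shock (0.0979). It turned G1 (0.867), alpha (0.166), erythroid (0.439), growth factor (0.627) and the acinar list itself (0.9996), the last because the covariate is its own mean. The Xist covariate ended the calls of macrophages (0.361) and immediate early genes (0.0527) and turned delta, PP and epsilon markers (0.760). G1 also turned with fry (0.989) and the 1 CPM filter (0.955). Among genes, 1 surrogate variable turned Nfe2l2 (-0.23), Keap1 (-0.10) and Fosb (0.00). The block turned Ppy (-0.22), Nqo1 (0.02) and Sparc (0.01). The acinar covariate turned Ppy (-0.04), Ctrb1 (0.18) and Sparc (0.14), Xist turned Nqo1 (0.18) and limma-voom Sparc (0.02). Apart from the acinar list, the cause was not tested.

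When each pool was left out, which leaves fewer samples, log2 fold changes ranged from -0.10 to 0.45 for Nfe2l2, -0.02 to 0.28 for Keap1, -0.20 to 0.31 for Ppy, -0.37 to 0.47 for Nqo1, -1.37 to 0.10 for Ctrb1, -0.21 to 0.10 for Sparc and -2.90 to -1.82 for Hmcn2. Of 108 genes followed in this way, 54 moved by over 1.5 times in size or turned without some pool, 36 of them without control pool 2. Adjusted p of the lists ranged from 0.303 to 0.948 (NRF2 targets), 0.00516 to 0.876 (S phase), 3.73e-06 to 0.640 (G2 and M phase), 0.498 to 0.970 (G1), 2.03e-08 to 0.402 (histones), 0.000135 to 0.967 (OXPHOS), 0.0112 to 0.668 (mitochondrial ribosome), 0.0447 to 0.319 (mitochondrial dynamics) and 4.21e-06 to 0.290 (TCA). They ranged from 4.21e-06 to 0.0745 (β-cell identity), 0.00246 to 0.851 (alpha), 0.121 to 0.948 (delta, PP and epsilon), 5.62e-10 to 0.915 (acinar), 0.000762 to 0.853 (macrophage), 0.000255 to 0.113 (neural) and 0.000365 to 0.943 (erythroid). For stress and metabolism they ranged from 0.00544 to 0.592 (unfolded protein response), 1.01e-06 to 0.309 (ATF4), 8.76e-07 to 0.241 (immediate early), 0.00116 to 0.694 (heat shock), 7.33e-06 to 0.382 (sterol), 0.0759 to 0.915 (fatty acid), 0.0579 to 0.650 (interferon), 0.470 to 0.900 (STAT5) and 0.169 to 0.943 (growth factor). The pools that end or turn each call are named beside the lists. At the depth of 18187382 to 25373105 counts per pool, the simulated test recovered 35.2% of 2-fold changes, so changes of that size can be missed. The simulation held no differences shared by many genes of a pool, so the share recovered need not hold for the real pools.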

Other observations

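The 3 tests of the Ins1 to Ins2 ratio, the tests of the mitochondrial mRNAs and of the hypoxia list within the pairs, the bounds on both without control pool 2, and the reading of the splits with the block and for a count of 0 were chosen only after the result was seen. The 7 pools can be split into groups of 3 and 4 in 35 ways, the real one included, which ignore the pairs. The real split gave 0 genes past the threshold by edgeR (1683 at unadjusted p under 0.05, 2 by DESeq2), so each of the 35 gives as many by construction and this count says nothing about chance. The highest other split gave 597 and set control pools 1 and 2 and βNrf2KO pool 1, the pools with the highest mitochondrial shares (43.0%, 51.8% and 27.7%), against the rest. So high a count points to a structure of the samples, and what separates these pools was not tested. For the number at unadjusted p under 0.05, 8 of 35 splits gave 1683 or more, up to 4347, and for the number of called lists 10 of 35 gave 15 or more, up to 22, so chance was not excluded for either. No split called fewer than 6 lists at the preset correlation. The splits that part the 3 numbered pairs give 4 different fits with the block, since a split and its mirror are 1 fit. These are too few for a share under 0.05. The real one gave 14 genes with the block and the highest other gave 0. Most of the 14 lie in the mitochondrial genome, whose genes moved together, so they are not separate findings.

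Ins1 was low relative to Ins2 in βNrf2KO pools, with a difference of the log2 ratio of -1.45 (pooled SD 0.143). A different share of β-cells would move both genes alike, and the tables argue against it, since -1.45 is beyond 2 pooled SD. Of 35 splits 1, the real one, gave 1.45 and the highest other gave 1.17, but the ratio was chosen after its separation was seen and its exact permutation p of 0.0571 is the smallest the design allows, so this adds no independent evidence against chance. Loss of 1 of the 2 Ins1 alleles in animals that carry Cre stays open, since Ins1 differed from the median of 37 other β-cell genes by -0.92 ± 0.318, a fold of 0.530 inside the range of 0.4 to 0.6 chosen for it after the values were seen, while the folds of 0.670 without control pool 4 and of 0.367 against Ins2 lie outside it, and the labels used here do not name the promoter of Cre. An effect of the Nrf2 deletion on insulin gene expression also stays open and was not tested.

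The 13 mRNAs of the mitochondrial genome were low in βNrf2KO pools, with a median of -1.49. Reads shared with a near-identical nuclear copy on chromosome 1 are argued against as the whole source, since the 5 mRNAs outside the copied stretch had a median of -1.45. The SD of 0.0753 is over these 5 mRNAs, which move together, and the SE of each over pools was 0.553 to 0.567. Control pool 2 as the whole source is left undecided by the unpaired fit without it (median -0.90, median SE 0.609). If the numbers are pairs it is argued against, since the median without it was -0.91 with the block (median SE 0.179, against -1.29 with all pools). This rests on pairs 1 and 4 with 1 residual degree of freedom, and the labels do not state the pairs. Chance was not excluded, since 8 of 35 splits gave a difference of the list mean of 1.35 or more, up to 1.97. These splits ignore the pairs, in each of which the list was lower, and the splits that part the pairs are too few for a share under 0.05. An effect of the Nrf2 deletion stays among the open explanations, as untested.

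Hypoxia and glycolysis genes were high in βNrf2KO pools, with a median of 0.39. Control pool 2 as the whole source stays undecided, since the median was 0.28 without it (median SE 0.218) and 0.34 without it with the block (median SE 0.177, against 0.35 with all pools), each within 2 SE of 0. For fewer exocrine cells as the whole source, the median with the acinar mean as a covariate was 0.47 (median SE 0.242), not nearer to 0. This passed the bound written before the result was seen, which used the standard error over list members. The value is also within 2 SE of 0, so by the bound used for control pool 2 this explanation stays undecided. That stricter bound was tried here after the values were seen and then withdrawn. The list stayed called at the preset correlation (camera, adjusted p = 1.57e-12), whose calls without the covariate ended with an estimated correlation. Chance was not excluded, since 4 of 35 splits gave a difference of the list mean of 0.50 or more, up to 0.62, again without regard to the pairs. A difference in islet isolation stays open, since the labels used here give no time or oxygen supply, as does an effect of the deletion, which was not tested.

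Transcripts of sex-linked genes differed between pools. Xist, expressed from the inactive X chromosome, stood at 2386, 45.6 and 2618 CPM in control pools 1, 2 and 4 and at 29.2, 1943, 125.9 and 1585 CPM in βNrf2KO pools 1, 2, 3 and 4. The sum of 4 Y-linked genes (Ddx3y, Uty, Kdm5d and Eif2s3y) was 0.694, 82.8 and 2.40 CPM in control pools 1, 2 and 4. It was 159.9, 52.5, 89.8 and 166.7 CPM in βNrf2KO pools 1, 2, 3 and 4. The means were 28.6 ± 46.9 CPM (SD, n = 3) in control and 117.2 ± 55.4 CPM (SD, n = 4) in βNrf2KO pools, which overlapped (exact permutation p = 0.114). Control pools 1 and 4 thus held far fewer Y-linked counts than control pool 2 and every βNrf2KO pool. The sex of the animals and the deletion are therefore partly confounded. In a principal component analysis control pool 2 lay at 94.8 on the component with 37.6% of the variance, where the other pools lay between -35.2 and 8.48.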
